A study of Mus musculus with 12 samples.

How the data were processed

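RNA-seq of mouse bone marrow neutrophils was used as a table of whole-number read counts per gene, 1 column per library. The authors sorted the cells as CD11b+, Ly6G+, Siglec F− and negative for the antigen encoded by Adgre1, from crushed hind limb bones and kept them for 2 h with vehicle or 100 ng/mL LPS, per the labels' protocols. RNA was purified on columns with DNase, ERCC spike-in RNA was added and an ultra-low input library kit was used, per the labels' protocols. The reads were aligned with STAR 2.6.0a to mm9 and counted with featureCounts, per the submitters' processing notes. The deposited counts are not normalized, as their whole numbers and unequal totals show. The annotation release, the strand setting, the version of featureCounts and the read filters are not given in the sources used here. Without a known strand setting, reads of a gene and an overlapping or antisense neighbour cannot be told apart. Reads shared between near-identical genes and processed copies can be split or lost, and such genes are named as uncertain.

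Each of the 12 columns was matched to a sample by its name and the sample title, which also gives genotype, treatment and library number; 0 further columns were left out. The table held 37310 genes, 32620 with a gene symbol, and genes with a symbol took 97.7 to 98.3% of the counts of a library. It held no spike-in entries, so spike-in scaling and the spike-in share were not analysed here. Gene names were taken from a separate list of gene names, matched to the identifiers of the table without their version number. Chromosome order was taken from a mouse annotation on GRCm38, which is not the build of the authors' alignment, and was used only for which genes neighbour each other; no coordinates are given.

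Total counts were 21875671, 26225169 and 21096154 in Control vehicle libraries 1, 2 and 3, 19023610, 21851003 and 22303772 in Control LPS, 21348792, 22582441 and 23812630 in Runx1KO vehicle and 21452163, 24871912 and 25443980 in Runx1KO LPS. TMM factors ranged from 0.700 (Runx1KO LPS 3) to 1.20. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only. Nothing in the labels says that libraries of a group came from separate mice, so p-values measure the spread between these libraries. By their Xist and Y-linked reads, given with the pairing check, the library numbered 2 of each group shared no mouse with those numbered 1 and 3; between 1 and 3 the spread may be technical. With 3 against 3 an exact permutation test of a single gene cannot give a two-sided p below 0.1, so tests borrowed spread across genes. No 2 libraries agreed within sampling noise over genes with at least 20 summed counts (lowest chi-square per degree of freedom 9.93).

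Genes were kept with edgeR 4.0.16 filterByExpr, which left 12917 (12325 with a symbol), scaled by TMM and tested with edgeR's quasi-likelihood test in 1 model of the 4 groups, in R 4.3.3. The 5 contrasts were LPS against vehicle in each genotype, Runx1KO against Control in each treatment, and the difference of the LPS responses. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors are those of the log2 fold change in this fit. A fold against a group at 0 counts used a floor of 3 counts over the group and is given as at least that fold; with 1 to 3 counts a ratio with a 95% counting interval is given. Log2 CPM values used a prior count of 2.

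The groups, contrasts, tests, 27 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the libraries compared, leaving out predicted genes and receptor segments. Chance gives no overlap to 10% of genes at 3 against 3. It adds up to 4 called members of each list per direction, and Runx1, Tnf, Cd14, Tlr4 and Il1b in every contrast. The lists cover cytokines and chemokines, NF-kB, Toll-like receptors, interferon-stimulated genes, immediate-early genes, primary, secondary and tertiary granules, adhesion receptors, oxidase and effector enzymes, cell cycle, ribosomal proteins, ribosome biogenesis, the unfolded protein response, apoptosis, glycolysis, mitochondrial transcripts and RUNX factors. They also cover monocytes, eosinophils, basophils and mast cells, the B lineage, T and NK cells, erythroid cells, megakaryocytes and platelets, progenitors and dendritic cells. Ribosomal protein genes have many processed copies that share reads. The values of 1 called gene are not reported here.

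Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 27 lists of a contrast. Of all camera calls, only the platelet list in both genotype comparisons held with an estimated correlation. The fry test was run too; its p tests whether the genes of a list move on balance one way and its mixed p whether they change in either direction, and neither compares a list with other genes. Fry's one-way test called the platelet list alone, with an adjusted p of 5.51e-04 with vehicle and 0.00144 with LPS. Its mixed test called 5 lists with vehicle (T and NK cells, glycolysis, platelets, B lineage and primary granule; largest adjusted p = 7.87e-04) and 6 with LPS, those 5 and the tertiary granule list (0.0118). Median, mean and camera direction of a list differed in sign in 29 of 135 tests, of which 0 were called.

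Library numbers occur in all 4 groups and may pair libraries. The check was the correlation of deviations from group means, fixed to count as pairing when every pair lay over 0.1. It ranged from 0.394 to 0.667 for LPS against vehicle in Control, 0.374 to 0.479 for the genotypes with vehicle and 0.429 to 0.565 with LPS, where the numbers pair. It did not hold for LPS against vehicle in Runx1KO or for the difference of responses. In all 4 groups the library numbered 2 had 0 Xist counts and reads of Y-linked genes, while those numbered 1 and 3 had 42.4 to 65.7 CPM of Xist. The main model had no block; the number as an additive block was an alternative.

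The other alternatives were a block within genotype, DESeq2 1.42.0, limma-voom, RLE scaling, library size alone, no low-count filter, a filter at 5 CPM in 3 libraries, a minimum fold of 1.5, a fit of only the 2 groups compared, and each library left out in turn. The scripts were tested on simulated counts of 12917 genes of which 200 were changed, 50 at each fold. A further set of genes was raised 2-fold as a shifted list, and calls of these were not counted as outside the changed genes. At 2-, 4-, 8- and 16-fold the share recovered was 0, 42, 62 and 86% for LPS in Control, 0, 36, 78 and 90% for LPS in Runx1KO, 2, 36, 74 and 88% for the genotypes with vehicle, 4, 36, 78 and 88% with LPS, and 0, 12, 40 and 64% for the difference of responses. For the genotypes with vehicle DESeq2 recovered 14, 64, 90 and 94%, with 28 of its 163 calls outside the changed genes, against 1 for edgeR.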

Results

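Bulk RNA-seq read counts were analysed for 12 libraries of neutrophils sorted from mouse bone marrow (strain C57BL/6; cells positive for CD11b and Ly6G and negative for Siglec F and for the macrophage antigen encoded by Adgre1). The libraries formed 4 groups of 3: Control and Runx1 knockout (Runx1KO) cells, each kept for 2 h with vehicle or with 100 ng/mL lipopolysaccharide (LPS), a bacterial cell wall component sensed through Tlr4. Runx1 is a DNA-binding transcription factor of blood cells, and the series asks whether it restrains the cytokine output of neutrophils after Toll-like receptor signalling. The series design text calls the Control material LKS- cells from the pooled marrow of a Runx1f/f and a Runx1f/- mouse, while the labels of each Control library describe sorted neutrophils. Which of these holds is not settled by the labels, and it bears on every comparison of the genotypes. LKS- cells are progenitors. With vehicle, the mean log2 level of the mature neutrophil list was −0.061, −0.012 and −0.28 in Control and −0.12, −0.027 and −0.19 in Runx1KO. Progenitor markers stood at −0.070, −0.88 and −0.017 against 0.22, 0.24 and 0.24. These levels argue against Control libraries made mainly of progenitors. Cell cycle genes were higher in Control, so a smaller share, and the pooling, stay open. Total gene counts ranged from 19023610 to 26225169 per library. The 10 most counted genes took 21.6 to 27.8% of the counts of a library. Mitochondrially encoded transcripts took 0.285 to 0.537%. Levels are given as CPM, counts scaled to a common library total, on TMM-scaled library sizes, as mean ± SD over the 3 libraries of a group.

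Runx1 (ENSMUSG00000022952.9) was counted in all 12 libraries. Its level was 36.8, 56.2 and 38.8 CPM in the Control vehicle libraries numbered 1, 2 and 3, and 32.3, 50.9 and 26.1 CPM in the Control LPS libraries. In the Runx1KO libraries it was 60.5, 68.3 and 75.4 CPM with vehicle and 58.3, 68.6 and 43.7 CPM with LPS. The group means were 43.9 ± 10.7 and 36.4 ± 12.9 CPM in Control and 68.1 ± 7.46 and 56.9 ± 12.5 CPM in Runx1KO (SD, n = 3). The log2 fold change of Runx1KO against Control was 0.63 (SE 0.29) with vehicle and 0.64 (SE 0.30) with LPS, and neither passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.656 and 0.492). A gene count sums reads over all exons, and the deleted part of the gene is not given in the sources used here. Reads from outside a deleted part check nothing, so these levels neither bear out nor contradict the genotype labels.

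The first comparison asked what LPS did to Control neutrophils. Transcripts of the NF-kB pathway and of cytokines stood higher as groups after LPS, while no single gene passed the test. All 24 measured genes of the NF-kB list, which holds the subunits of this transcription factor and the inhibitors it induces, had a positive log2 fold change (median 1.24). The same held for 27 of 31 cytokine and chemokine genes (median 1.22; 1.27 with Csf2 set at its bound and Cxcl5, at 0 counts in both groups, left out) and 16 of 18 genes of the list of oxidase subunits and inducible effector enzymes (median 0.74). Of these 3 lists 0 members passed the test over all genes and 0 when adjusted over the list alone. Tnf, the cytokine tumour necrosis factor, averaged 634 ± 627 CPM with vehicle and 1696 ± 375 CPM with LPS (log2 fold change 1.42, SE 1.22, edgeR adjusted p = 1). Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, was not named by the rule and did not pass the test. It averaged 2382 ± 1875 and 4675 ± 462 CPM. The log2 fold change of Cd14, the LPS co-receptor, was 1.48 (SE 1.01), that of the cytokine gene Il1b was 0.90 (SE 0.81) and that of Tlr4 was −0.43 (SE 0.49), each with an adjusted p of 1. Runx1 had a log2 fold change of −0.27 (SE 0.29).

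By camera, which compares a list with all other genes, the adjusted p was 1.36e-17 for the NF-kB list, 6.39e-12 for the cytokine list and 2.26e-07 for the oxidase and effector list. Each of these had an adjusted p = 0.606 with an estimated correlation between genes. Smaller shifts of lists were called for apoptosis regulators (median 0.20, 16 of 21 positive, adjusted p = 0.0238), immediate-early and MAPK feedback genes (0.29, 20 of 26, 0.0238), Toll-like receptors and their adaptors (0.18, 23 of 32, 0.0348) and dendritic cell markers (0.33, 9 of 10, 0.0341). The RUNX and core-binding factor list was lower, with 0 of 8 positive (median −0.27, adjusted p = 0.0338). With an estimated correlation the adjusted p was 0.606 for apoptosis regulators and the RUNX list, 0.765 for the receptors and dendritic cell markers and 0.811 for immediate-early genes. The dendritic cell call also ended with the replicate number as a block (camera adjusted p = 0.0501). Dusp6, a phosphatase that turns off ERK and was chosen here after its values were seen, was the only member of these 8 lists past the test adjusted over the list alone. It averaged 111 ± 23.8 CPM with vehicle and 46.2 ± 17.2 CPM with LPS (log2 fold change −1.27, SE 0.30, adjusted p over all genes = 1).

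Of 12917 genes tested in Control cells, edgeR called 0 higher and 0 lower after LPS. At an unadjusted p under 0.05 there were 78, of which 52 were higher and 26 lower, against 646 expected by chance. DESeq2 and limma-voom also called 0. The size of the shift differed by library number: the mean level of the NF-kB list was higher with LPS by 0.40, 0.53 and 3.93 log2 in the pairs numbered 1, 2 and 3, and that of the cytokine list by 0.40, 0.83 and 3.10. With the 4 libraries numbered 3 left out, the camera adjusted p was 0.501 for Toll-like receptors, 0.567 for apoptosis regulators, 0.374 for dendritic cell markers and 0.370 for the RUNX list. With those numbered 2 left out it was 0.121 for immediate-early genes and 0.0622 for the RUNX list.

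**Figure D1:**
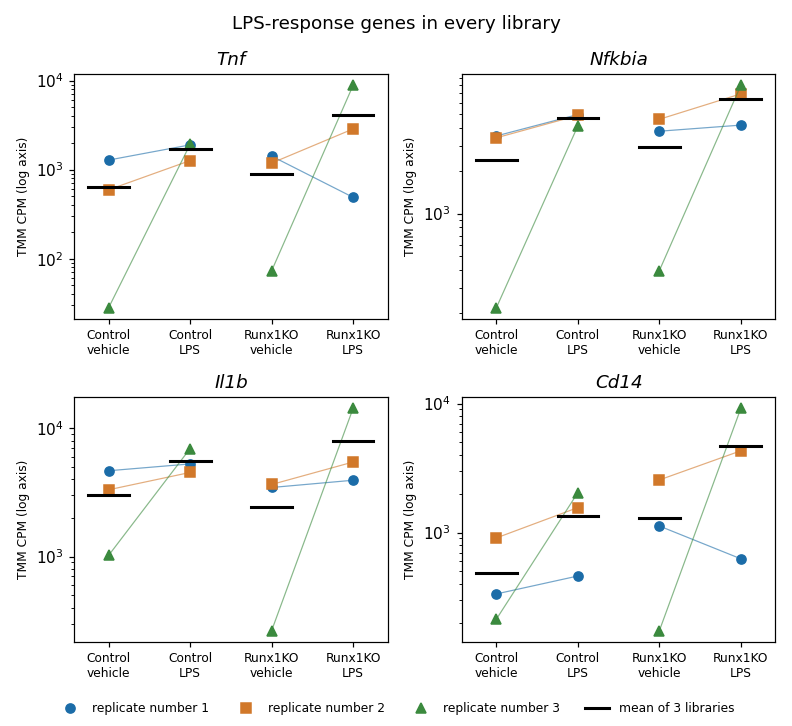
TMM-scaled CPM of Tnf, Nfkbia, Il1b and Cd14 on a log axis in the 4 groups; each marker is a library, its shape and colour give the library number, lines join vehicle and LPS libraries of the same number and genotype, and black bars are means of 3. The vehicle libraries numbered 3 had the lowest Tnf level of their groups, 28.2 CPM in Control and 73.0 CPM in Runx1KO. Nfkbia was not named by the rule for named genes.

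The second comparison asked the same of Runx1KO neutrophils. Cytokine, immediate-early, oxidase and NF-kB transcripts again stood higher as groups with LPS, and so did ribosomal protein and mitochondrially encoded transcripts, while edgeR called no single gene. Positive log2 fold changes were found for 30 of 31 cytokine genes (median 1.78), 24 of 24 NF-kB genes (1.15), 24 of 26 immediate-early genes (0.81) and 17 of 18 oxidase and effector genes (1.19). The same was true of 75 of 77 cytosolic ribosomal protein genes (0.39) and 15 of 15 mitochondrially encoded transcripts (0.53). Tnf averaged 892 ± 719 CPM with vehicle and 4071 ± 4313 CPM with LPS (log2 fold change 2.19, SE 1.25, edgeR adjusted p = 0.873). Ccl4, a chemokine chosen here after its values were seen, averaged 103 ± 121 and 1908 ± 2753 CPM (log2 fold change 4.22). The log2 fold change was 1.69 for Il1b (SE 0.82), 1.87 for Cd14 (SE 1.02), 0.14 for Tlr4 (SE 0.49) and −0.26 for Runx1 (SE 0.29). That of Tlr4 was −0.18 with library size alone as scaling. Adjusted over the list alone, Myc, a transcription factor of growth, was higher (log2 fold change 2.62, SE 0.60) and Dusp6 lower (−1.31, SE 0.30) among the immediate-early genes. The mast cell protease gene Cpa3 was higher in its list on 3 counts over the vehicle libraries and 19 with LPS (count ratio 7.57, 95% counting interval 2.23 to 39.9); these 3 were chosen after their values were seen, and their adjusted p over all genes was 0.873.

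The camera adjusted p was 3.83e-11 for cytokines, 6.88e-05 for NF-kB, 1.2e-05 for immediate-early genes, 7.73e-06 for oxidase and effectors, 7.72e-15 for ribosomal proteins and 2.98e-06 for mitochondrial transcripts. With an estimated correlation the adjusted p was 0.758 for NF-kB and 0.689 for each of the other 5 lists. The edgeR test called 0 genes higher and 0 lower (smallest adjusted p = 0.873), with 676 at an unadjusted p under 0.05, of which 424 were higher and 252 lower, against 646 expected by chance. By limma-voom 0 genes were called, and by DESeq2 0 higher and 1 lower, the immunoglobulin gene Ighg2c (DESeq2 log2 fold change −4.79, adjusted p = 0.00506; edgeR adjusted p = 0.873). The mean level of the NF-kB list differed between LPS and vehicle by −1.45, 0.63 and 4.56 log2 in the pairs numbered 1, 2 and 3. The difference was −0.57, 0.77 and 5.72 for cytokines, −0.017, 0.31 and 2.53 for immediate-early genes and −0.37, 0.67 and 3.36 for oxidase and effectors. The pair numbered 1 was thus lower with LPS in each of these lists. With the 4 libraries numbered 3 left out, the adjusted p was 0.648 for cytokines and immediate-early genes and 0.486 for oxidase and effectors, whose median in the voom fit turned to −0.033, and the NF-kB list turned (median −0.50, adjusted p = 0.419). Scaling by library size alone moved the median of all genes from −0.020 to −0.14 in the Control comparison, from 0.028 to −0.28 in the Runx1KO comparison and from 0.048 to −0.15 in their difference.

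**Figure D2:**
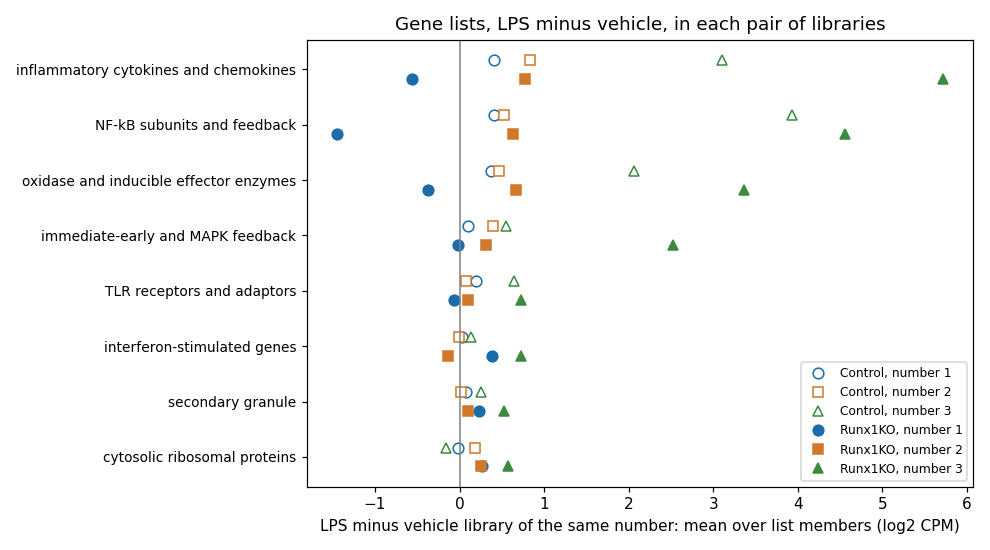
Mean log2 level of 8 gene lists with LPS minus that with vehicle, for each pair of libraries of the same number; open markers are Control and filled markers Runx1KO, and 0 marks equal levels. In the NF-kB list the pairs numbered 3 stood at 3.93 (Control) and 4.56 (Runx1KO), and the Runx1KO pair numbered 1 stood at −1.45.

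The responses to LPS of both genotypes shared 0 called genes, since edgeR called 0 in each. At an unadjusted p under 0.05 and in the same direction they shared 25 genes, against 2.04 expected of independent lists. The log2 fold changes of LPS in Control and in Runx1KO cells correlated across genes with r = 0.482; genes are not independent replicates, and the libraries compared were not shared. Libraries of the same number resembled each other across genotypes, so these lists were not independent.

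The third comparison asked how Runx1KO neutrophils differed from Control with vehicle. Transcripts known from megakaryocytes and platelets rose as a group, a small set of other genes rose from near 0, and several genes known from other blood lineages fell. Itga2b, the integrin subunit CD41 of platelets, rose from 0.763 ± 0.336 to 10.0 ± 1.68 CPM (log2 fold change 3.70, SE 0.49, edgeR adjusted p = 0.00501). The platelet chemokine genes Pf4 (log2 fold change 4.91, SE 0.78) and Ppbp (6.22, SE 1.17) also rose, and so did Treml1, a platelet receptor with a count ratio of 111 (95% counting interval 30.5 to 925). The adjusted p of these 3 was 0.0118, 0.0290 and 0.0152. Of 10 measured members of this list 4 rose over all genes and 6 did not pass; adjusted over the list alone 9 were higher and 1, Itgb3, was lower. The replicate block called 6 higher.

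Among the genes named by the rule and in none of the lists, the largest rises were those of Fam19a4 (log2 fold change 5.65, SE 1.06), a secreted chemokine-like protein, from 0.381 to 19.5 ± 14.5 CPM, and Arhgap12 (5.03, SE 0.69) from 1.25 to 41.2 ± 18.2 CPM. Foxo1, a forkhead transcription factor, rose from 4.42 ± 0.968 to 30.3 ± 1.20 CPM, and Ctla2a, an inhibitor of cysteine proteases, from 2.18 ± 0.925 to 19.7 ± 1.57 CPM (adjusted p = 0.00331 for both). Lrrc8b (3.79), Dmpk (2.53) and Tsc22d1 (2.34) rose as well. Stfa2, a cysteine protease inhibitor, had a log2 fold change of 2.66 (SE 0.41), but it belongs to a family of near-identical genes whose reads could be split, and its value is uncertain. Cd3d, a chain of the T cell receptor complex, fell from 38.5 ± 7.89 to 2.40 ± 0.691 CPM (log2 fold change −4.0, SE 0.30, adjusted p = 2.09e-04). Other members of the T and NK cell list did not pass, and 5 of its 8 members had a positive log2 fold change. Nrp1, a receptor of semaphorins, fell from 23.1 ± 7.61 to 1.41 ± 0.504 CPM. Ifitm1, an interferon-inducible membrane protein, fell from 151 ± 60.2 to 16.1 ± 3.01 CPM. The orphan receptor gene Gpr141 (−4.91), Tex15 (−4.02), Haao (−3.50) and Amer2 (−2.80) fell too. Ldha and Ldhc, subunits of lactate dehydrogenase, had log2 fold changes of −2.64 (SE 0.26) and −5.37 (SE 0.85). Cd63, a granule membrane protein, had −1.91 (SE 0.25). Ldha and Cd63 have processed copies in the genome that could take or give reads, and their values are uncertain.

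**Figure D3:**
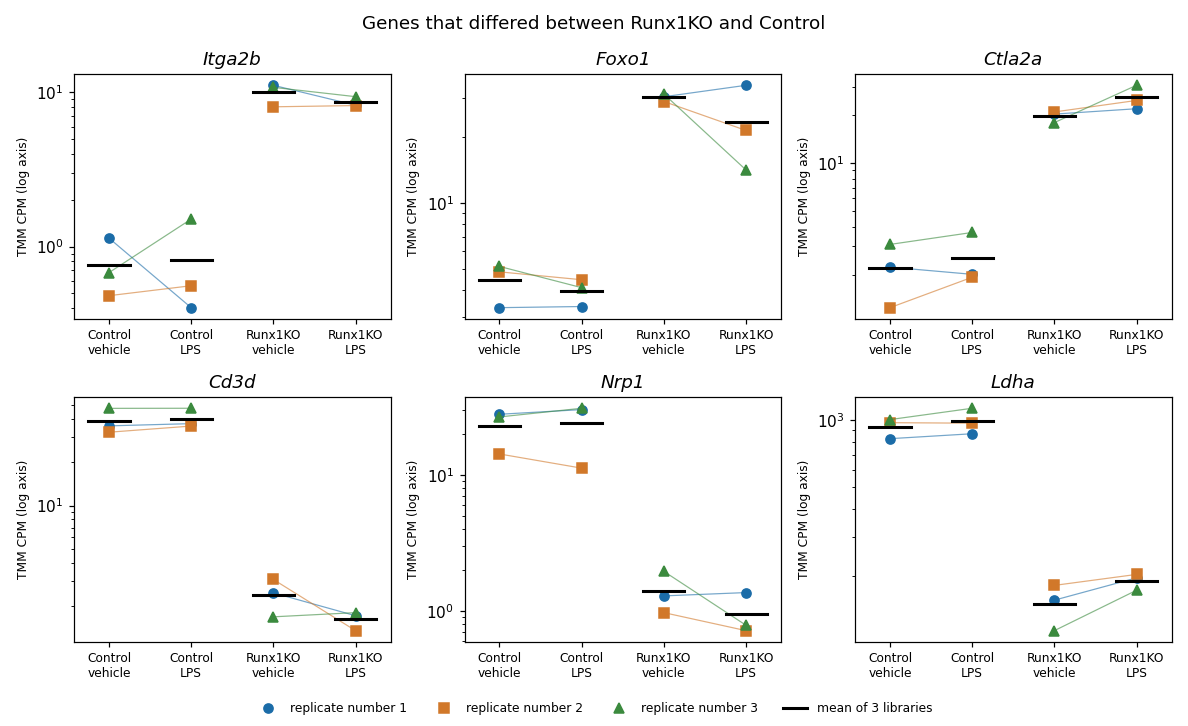
TMM-scaled CPM of Itga2b, Foxo1, Ctla2a, Cd3d, Nrp1 and Ldha on a log axis in the 4 groups; each marker is a library and black bars are means of 3. Cd3d averaged 38.5 and 40.1 CPM in Control and 2.40 and 1.62 CPM in Runx1KO, with vehicle and LPS.

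Transcripts of basophil proteases were counted in Control libraries and were at 0 counts in Runx1KO libraries. Prss34, a basophil protease, was at 8.97 CPM in Control vehicle and at 0 counts in Runx1KO vehicle, at least 224-fold lower (edgeR adjusted p = 0.0197). Mcpt8, another basophil protease, was at least 64.5-fold lower (adjusted p = 0.0444). Over the 6 measured members of this list 2 fell and 4 did not pass; adjusted over the list alone 4 were lower, and the median was −5.15, or −3.71 with 3 genes at their bound. By fry's one-way test the list passed only with the replicate block (adjusted p = 0.0288). Among 12 B lineage genes 2 fell, of which Ms4a1, the surface protein CD20, was at least 43.2-fold lower (adjusted p = 0.00634). Adjusted over the list alone 6 were lower, and with the replicate block 4 (list median −2.13). By fry's one-way test this list too passed only with the block (adjusted p = 0.00527). The eosinophil ribonuclease gene Ear2 fell (−6.25, SE 1.28). Its 12 counts in Runx1KO vehicle all came from library 3, and without it the fitted value, then against 0 counts, was −11.05 and is no bound. Of this list 6 of the 7 measured eosinophil genes did not pass and Ccr3 was higher and Ear1 and Ear2 lower when adjusted over the list alone. The camera adjusted p was 6.81e-04 for the basophil and mast cell list and 1.03e-06 for the B lineage list, and for both the adjusted p was 0.515 with an estimated correlation. For the eosinophil list (median −1.06) it was 0.628.

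Megakaryocyte and platelet genes (median 3.07, 9 of 10 positive, camera adjusted p = 1.12e-15) were the only list whose call held with an estimated correlation (adjusted p = 0.0157), and this call ended with the replicate block and an estimated correlation together (adjusted p = 0.128). Other lists were called by camera with its preset correlation alone. Cell cycle genes were lower with 0 of 36 positive (median −0.38, adjusted p = 1.39e-07; adjusted p = 0.551 with an estimated correlation). Glycolysis genes were lower (median −0.23, 3 of 20 positive, 0.00209; adjusted p = 0.551 with an estimated correlation), with Ldha the 1 member past the test. Ribosomal protein genes were higher (0.17, 66 of 77, 3.29e-04), as were erythroid genes (1.34, 14 of 15, 0.00426; the 1 member higher when adjusted over the list alone was Gata1), and both had an adjusted p = 0.940 with an estimated correlation. Progenitor genes were higher (0.27, 8 of 10, 0.0471; adjusted p = 0.515 with an estimated correlation). With the libraries numbered 1 left out the erythroid and progenitor calls ended (camera adjusted p = 0.0786 for both), and with those numbered 2 left out the ribosomal protein (0.982, with a voom median of −0.020), glycolysis (0.173), erythroid (0.684) and progenitor (0.292) calls ended. The progenitor call also ended with library size alone (0.0696).

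Granule and mature neutrophil genes did not pass camera or fry's one-way test as lists with vehicle. Fry's mixed test, which asks for change in either direction, called the primary granule list (adjusted p = 7.87e-04). The secondary granule list had a median of −0.31 (camera adjusted p = 0.105), the tertiary granule and mature neutrophil list −0.065 (0.909), the adhesion and chemoattractant receptor list 0.018 (0.906) and the primary granule list 0.37 (0.686). In the last, Cd63 was the 1 member past the test, and 4 members (Cd63, Ms4a3, Prss57 and Fcnb) were lower when adjusted over the list alone, so that median and mean had opposite signs. Neither did inflammatory lists pass: cytokines (0.75, 0.178), NF-kB (0.33, 0.165), Toll-like receptors (0.19, 0.165), interferon-stimulated genes (0.089, 0.628), immediate-early genes (−0.14, 0.715) and oxidase and effectors (0.034, 0.914). The remaining medians and camera adjusted p were 0.090 and 0.628 for ribosome biogenesis, 0.048 and 0.491 for the unfolded protein response, 0.25 and 0.161 for apoptosis regulators, −0.14 and 0.278 for mitochondrial transcripts, −0.053 and 0.715 for the RUNX list, 0.64 and 0.659 for monocytes, 0.40 and 0.722 for T and NK cells (fry's mixed adjusted p = 3.70e-07), and −0.13 and 0.969 for dendritic cells. Without the libraries numbered 3, cytokines (voom median 0.91, camera adjusted p = 4.68e-04) and NF-kB genes (0.55, 0.0322) were called higher. Without those numbered 1, interferon-stimulated genes were called higher (0.42, 0.0167) and secondary granule genes lower (−0.36, 0.0251). Mitochondrial transcripts were called lower without those numbered 2 (−0.33, 0.00447). The cytokine median ranged from −0.18 to 0.91 over the fits without 1 number.

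In total edgeR called 45 genes higher and 78 lower with vehicle, 36.6% of them higher; with library size alone the counts were 45 and 50, 47.4% higher. With the replicate number as a block, 114 were higher and 201 lower, among them all 123 genes called without it. Tnf (log2 fold change 0.49, SE 1.20, adjusted p = 1.00), Cd14 (1.40, 0.954), Il1b (−0.29, 1.00) and Tlr4 (0.67, 0.960) did not pass. Leaving out any 1 library of this comparison moved both counts by more than 1.5 times: without Control vehicle 1, 2 or 3 the calls were 15 higher and 32 lower, 20 and 50, and 18 and 34, and without Runx1KO vehicle 1, 2 or 3 they were 23 and 34, 27 and 35, and 29 and 37. Leaving out 1 library moved the fold of Fam19a4 (6.36 log2 without Control vehicle 2), Ldhc (−4.71 without Control vehicle 3 and −6.20 without Runx1KO vehicle 2), Gpr141 (−5.74, without Runx1KO vehicle 2), Tex15 (−5.03, without Runx1KO vehicle 1) and Amer2 (−3.72, without Runx1KO vehicle 3) by over 1.5 times. Without Control vehicle 3 the fitted values of Prss34 and Mcpt8, against 0 counts and no bounds, went from −10.67 to −10.01 and from −8.88 to −8.16. Both Control counts of Treml1 came from Control vehicle 1, without which no ratio can be had. With all 4 libraries numbered 1, 2 or 3 left out, which leaves 2 per group, the calls were 0 higher and 2 lower, 0 and 1, and 3 and 3, and 27, 27 and 23 of the 27 named genes lost their call. Of 27 named genes 12 kept their call in all 6 fits with 1 library left out: Arhgap12, Cd3d, Cd63, Ctla2a, Dmpk, Foxo1, Gpr141, Ifitm1, Itga2b, Ldha, Ms4a1 and Nrp1 (highest adjusted p = 0.0405, Dmpk). The other 15 lost it in at least 1. Mcpt8, Ppbp and Tsc22d1 lost it in all 6, and Ear2, Fam19a4, Haao and Lrrc8b in 5. Amer2, Prss34 and Tex15 lost it in 4, Pf4, Stfa2 and Treml1 in 2 and Ldhc in 1. Among them the highest adjusted p was 0.0607 for Pf4, 0.0722 for Treml1 and 0.151 for Tsc22d1 (without Control vehicle 3), 0.0643 for Stfa2, 0.141 for Fam19a4, 0.150 for Ppbp and 0.180 for Lrrc8b (without Control vehicle 1), 0.0727 for Prss34, 0.0771 for Ldhc, 0.141 for Mcpt8 and 0.170 for Ear2 (without Runx1KO vehicle 1), and 0.126 for Tex15, 0.158 for Haao and 0.187 for Amer2 (without Runx1KO vehicle 2).

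The fourth comparison asked how Runx1KO neutrophils differed from Control after LPS. Megakaryocyte and platelet genes rose as a group, Cd3d and Nrp1 fell, and 1 cytokine gene, Il27, rose. Itga2b was at 0.821 ± 0.598 CPM in Control and 8.62 ± 0.662 CPM in Runx1KO (log2 fold change 3.38, SE 0.48, edgeR adjusted p = 0.00863), and Treml1 had a log2 fold change of 5.21 (SE 0.98, 0.0319). Of 10 platelet genes 2 rose and 8 did not pass; adjusted over the list alone 8 were higher and 1 lower, and the replicate block called 4 higher and 1 lower. Il27, which encodes a subunit of interleukin-27, rose from 3.50 ± 0.721 to 21.8 ± 12.6 CPM (log2 fold change 2.64, SE 0.52, 0.0390). Its call was lost in 5 of the 6 fits with 1 library left out. It was the 1 called member of 31 cytokine genes, of which 30 did not pass; adjusted over the list alone 4 were higher (Il27, Cxcl5, Ccl2 and Ccl7), and the block called 2. Tnf (log2 fold change 1.26, SE 1.22, adjusted p = 0.837), Cd14 (1.80, 0.626) and Il1b (0.50, 0.924) did not pass. Tlr4 had a log2 fold change of 1.24 (SE 0.50, adjusted p = 0.410) and passed only with the replicate block (adjusted p = 0.0455).

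Fam19a4 rose from 1.01 to 76.6 ± 77.2 CPM, Arhgap12 from 1.38 to 31.3 ± 25.1 CPM and Ctla2a from 2.53 ± 0.987 to 25.8 ± 4.52 CPM. Gimap9 (log2 fold change 3.12), the transporter gene Abcg2 (3.10) and Dmpk (2.77) rose as well. Stfa2 (3.43), Stfa3 (3.27) and Stfa2l1 (1.62) had positive values that are uncertain because these genes are near-identical. Cd3d fell from 40.1 ± 6.43 to 1.62 ± 0.240 CPM (log2 fold change −4.63, SE 0.31, adjusted p = 6.19e-05) and Nrp1 from 24.3 ± 11.3 to 0.959 ± 0.358 CPM. Gpr141 (−4.32), Amer2 (−3.78), Tex15 (−3.48) and Haao (−3.44) fell too. The log2 fold changes of Ldha (−2.38), Ldhc (−6.24), Cd63 (−1.67) and the hair keratin gene Krt83 (−3.47) are uncertain where near-identical genes share reads. Prss34 was at least 227-fold lower (adjusted p = 0.0191), and Ms4a1 was lower by a count ratio of 79.0 (95% counting interval 13.8 to 3160, adjusted p = 0.0191).

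By camera the platelet list (median 2.72, adjusted p = 5.36e-12) again was the only one whose call held with an estimated correlation (adjusted p = 0.0425), and this call ended with the block and an estimated correlation together (adjusted p = 0.205). Ribosomal protein genes were higher (0.58, 76 of 77 positive, 2.78e-22), and so were progenitor genes (0.81, 9 of 10, 0.0220), while B lineage genes were lower (−1.85, 2 of 12, 1.94e-06; 1 fell and 8 were lower when adjusted over the list alone, 4 with the block; fry adjusted p = 0.010 with the block, 0.188 without). These 3 had an adjusted p = 0.529 with an estimated correlation. Cytokines (median 1.43, 27 of 31 positive, 0.00534), interferon-stimulated genes (0.44, 21 of 30, 0.0454), mitochondrial transcripts (0.33, 15 of 15, 0.0154) and erythroid genes (1.42, 15 of 15, 4.43e-04) were higher, with an adjusted p = 0.732 for each with an estimated correlation. Cell cycle genes (−0.35, 2 of 36 positive, 2.24e-06) and glycolysis genes (−0.20, 7 of 20, 0.0116) were lower, with an adjusted p = 0.730 for both with an estimated correlation. With the libraries numbered 2 left out, the calls of cytokines, interferon-stimulated, erythroid and progenitor genes ended (adjusted p = 0.135 for each). With those numbered 3 left out, the calls of cytokines (0.283), interferon-stimulated genes (0.185), glycolysis (0.162) and mitochondrial transcripts (0.644) ended. Without those numbered 1, further lists were called higher by camera. These were immediate-early genes (voom median 0.61, adjusted p = 0.00395), oxidase and effectors (0.48, 0.0170) and apoptosis regulators (0.44, 0.0208). Basophil and mast cell genes (median −3.56, or −2.02 with genes at their bound; 1 fell, 3 lower when adjusted over the list alone; 0.151; voom median 0.22 without the libraries numbered 3), eosinophil genes (−0.28, 0.504), tertiary granule genes (0.23, 0.278) and primary granule genes (0.66, 0.426) did not pass camera. Without the libraries numbered 2, camera called the basophil and mast cell list lower (voom median −1.52, adjusted p = 0.00197). Fry's mixed test called the tertiary (adjusted p = 0.0118) and primary granule lists (0.00285).

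With LPS edgeR called 45 genes higher and 74 lower, and with the replicate block 117 higher and 185 lower, among them all 119 called without it. With only these 2 groups in the fit the counts were 13 and 14. Without Control LPS 1, 2 or 3 the calls were 26 higher and 40 lower, 15 and 46, and 15 and 34. Without Runx1KO LPS 1 they rose to 56 and 79, and without Runx1KO LPS 2 or 3 they were 26 and 27, and 28 and 34. The fold moved by over 1.5 times for Fam19a4 (4.99 log2) and Gpr141 (−5.35) without Runx1KO LPS 3, Arhgap12 (3.62) without Runx1KO LPS 1, Ldhc (−7.0) and Krt83 (−4.71) without Runx1KO LPS 2 and Itga2b (4.16) without Control LPS 3. All 5 Control counts of Treml1 came from Control LPS 1 and the 1 Runx1KO count of Ms4a1 from Runx1KO LPS 1, without which their fitted values are no bounds. Without Control LPS 3 the fitted value of Prss34, also no bound, went from −10.91 to −10.21. With all 4 libraries numbered 1, 2 or 3 left out the calls were 1 and 2, 0 and 4, and 11 and 14, and 23, 22 and 13 of the 24 named genes lost their call. Of 24 named genes 9 kept their call in all 6 fits with 1 library left out: Cd3d, Ctla2a, Dmpk, Itga2b, Ldha, Ldhc, Nrp1, Stfa2 and Stfa3 (highest adjusted p = 0.0406, Itga2b). The other 15 lost it in at least 1. Tex15 lost it in all 6, Gimap9, Haao, Il27, Krt83 and Ms4a1 in 5 and Treml1 in 4. Fam19a4, Prss34 and Stfa2l1 lost it in 3, Abcg2 and Amer2 in 2, and Arhgap12, Cd63 and Gpr141 in 1. The highest adjusted p was 0.0514 for Arhgap12 and 0.0645 for Stfa2l1 (without Control LPS 2), 0.0995 for Fam19a4 and 0.117 for Haao (without Control LPS 1), and 0.0553 for Abcg2, 0.113 for Treml1, 0.162 for Il27 and 0.169 for Gimap9 (without Control LPS 3). It was 0.0520 for Cd63, 0.0669 for Gpr141 and Amer2, 0.0685 for Prss34 and 0.0999 for Ms4a1 (without Runx1KO LPS 2), and 0.151 for Tex15 and 0.170 for Krt83 (without Runx1KO LPS 3).

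The differences between genotypes recurred in both treatments. Of the called genes 29 were higher with vehicle and with LPS, against 0.157 expected of independent lists, and 58 were lower in both, against 0.447. The log2 fold changes correlated across genes with r = 0.768. These comparisons shared no library, but libraries of the same number resembled each other across treatments, so they were not independent.

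The last comparison asked whether the response to LPS differed between genotypes. No gene passed, and the cytokine genes of the question were among those that did not. The difference of the log2 fold changes, Runx1KO minus Control, was 0.77 for Tnf (SE 1.70), 0.79 for Il1b, 0.39 for Cd14 and 0.57 for Tlr4, and 0.011 for Runx1 (SE 0.41), with an edgeR adjusted p of 1.00 for each. The Tnf value turned to −0.37 by limma-voom. Cytokine genes had a median difference of 0.79 with 26 of 31 positive (camera adjusted p = 0.152), and NF-kB genes 0.10 with 17 of 24 positive (0.238, with the direction of camera's test lower). The direction of both lists depended on which library numbers were used. In the voom fit the cytokine median was 1.36 without the libraries numbered 1 (camera adjusted p = 3.61e-05) and −0.51 without those numbered 3 (0.0189), and with library size alone it was 0.35 (3.49e-04). The NF-kB median was 0.29 without the libraries numbered 1 and −0.92 without those numbered 3 (6.68e-05). In edgeR 0 genes were called, with 77 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. By camera, the difference of responses was called for 5 lists, with LPS minus vehicle higher in Runx1KO than in Control: ribosomal proteins (median difference 0.37, 76 of 77 positive, adjusted p = 1.85e-16), mitochondrial transcripts (0.50, 15 of 15, 1.16e-06), immediate-early genes (0.42, 22 of 26, 0.00435), primary granule genes (0.31, 13 of 14, 0.0280; medians −0.19 in Control and 0.25 in Runx1KO, neither called) and basophil and mast cell genes (0.47, 4 of 6, 0.0453). With an estimated correlation their adjusted p lay between 0.913 and 0.990, and 0 of their members passed the gene test, over all genes or adjusted over the list alone.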

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

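The tests of swapped libraries, monocytes and stimulated vehicle cells were chosen only after the result was seen, as were the fits without the libraries of 1 number.

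Camera's test of the difference itself singled out 5 lists whose response to LPS differed between genotypes. The cytosolic ribosomal protein list (adjusted p = 1.85e-16) differed between LPS and vehicle by −0.021, 0.19 and −0.16 log2 in the Control pairs numbered 1, 2 and 3 and by 0.27, 0.25 and 0.57 in the Runx1KO pairs. The mitochondrially encoded list (1.16e-06) differed by −0.022, 0.41 and −0.38 in Control and 0.35, 0.30 and 0.90 in Runx1KO. The primary granule list (0.0280) differed by −0.32, 0.099 and −0.26 in Control and 0.30, 0.18 and 0.19 in Runx1KO, and its adjusted p was 0.193 without the libraries numbered 1. The immediate-early and MAPK feedback list (0.00435) differed by 0.098, 0.39 and 0.55 in Control and −0.017, 0.31 and 2.53 in Runx1KO, and without the libraries numbered 3 its median turned to −0.057 (adjusted p = 0.464). The mitochondrial call also ended without the libraries numbered 3 (0.464). The basophil and mast cell list (0.0453), of whose 6 members 3 were at or under 3 counts in both Runx1KO groups, lost its call without the libraries of any 1 number (0.144, 0.0526 and 0.263 without 1, 2 and 3). None of the 5 calls held with an estimated correlation (adjusted p from 0.913 to 0.990), and fry's one-way test gave an adjusted p of 1.00.

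These differences rest on how far the vehicle and LPS libraries stood apart, and the vehicle libraries numbered 1 and 2 of both genotypes stood near the LPS libraries in NF-kB and cytokine transcripts. An exchange of vehicle and LPS libraries within a number would, alone, leave 1 library of each pair as low as the vehicle libraries numbered 3. None of the 8 libraries numbered 1 or 2 was that low in the mean level of the NF-kB list. The lowest, Runx1KO LPS 1 at −1.30 log2, lay 1.09 above the higher vehicle library numbered 3, and the 2 vehicle libraries numbered 3 differed by 0.282. These are the NF-kB levels that define the pattern, so they cannot tell whether any single pair was exchanged. The monocyte list was lower in vehicle libraries 1 and 2 than in 3, by differences of −0.821 in Control and −0.838 in Runx1KO. This argues against monocytes as the source of the high levels of vehicle libraries 1 and 2. It does not exclude monocytes in the sorted cells, of which the gate against the Adgre1 antigen would remove those that carry it. The most abundant genes of the list averaged 1323 and 702 CPM (Ly6c2), 148 and 269 CPM (Csf1r) and 35.6 and 98.3 CPM (Adgre1) with vehicle. In LPS libraries 1, 2 and 3 the monocyte list stood at −0.48, −0.59 and 0.54 log2 in Control and −0.44, 0.45 and 1.21 in Runx1KO. The cytokine list stood there at −0.035, 0.22 and 0.78 and at −0.67, 1.70 and 3.13, and a share of monocytes in these was not tested. Stimulation of the vehicle cells before lysis stays open, since the mean NF-kB level of the 4 vehicle libraries numbered 1 and 2 lay 2.72 log2 above the 2 numbered 3, a value that only restates the pattern. An exchange of the Runx1KO pair numbered 1 is a hypothesis that may also play a part: of 100 genes with the smallest p for LPS in the other 5 pairs 32% moved the same way in this pair, against 77 to 94% in the others, but the idea came from the same values, the labels were kept and no biological explanation was tested.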

How the results depend on the processing

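The fits without all 4 libraries of 1 number and the list tests with library size alone were chosen after seeing the data. Scaling by spike-in and the spike-in share were not run, because the table used here held no spike-in entries. In simulated groups of 3 the edgeR test recovered at most 4% of 2-fold changes. For LPS it recovered 36 to 42% of 4-fold and 86 to 90% of 16-fold changes. The simulated genes were drawn at random and carried no effect of library number. Genes with a wide spread between libraries, such as Tnf, may be recovered less often, so the simulation does not settle why the counts were 0. The counts of 0 for LPS in Control and for the difference of responses held under every alternative run, as did the overlap of 0 between LPS responses. For LPS in Runx1KO the edgeR count of 0 held under each edgeR and limma-voom alternative, and DESeq2 called 1 gene lower. Where no reason is given, the cause was not tested.

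With the replicate number as a block, the genotype calls were 114 higher and 201 lower with vehicle and 117 and 185 with LPS. DESeq2 called 158 and 228 with vehicle and 175 and 226 with LPS. The filter at 5 CPM, which tests fewer genes, left 20 higher and 48 lower with vehicle and 49 lower with LPS. Library size alone left 50 lower with vehicle. A minimum fold of 1.5, a stricter question, left 42 lower with vehicle and 43 lower with LPS. With only the 2 groups compared in the fit, and so fewer libraries, 13 were higher and 14 lower with LPS. Across fits that left out 1 library or all libraries of 1 number, the calls with vehicle ranged from 0 to 29 higher and 1 to 50 lower, and with LPS from 0 to 56 higher and 2 to 79 lower; these fits have fewer libraries. In the contrasts whose numbers pair, the block changed no other call of a named gene, camera or fry beside those given in the comparisons. In the contrasts whose numbers did not pass the pairing check (lowest correlation 0.0058 for LPS in Runx1KO and −0.053 for the difference of responses), the block and the block within genotype called 0 genes, as without it. For LPS in Runx1KO they gave 1145 and 1261 genes at an unadjusted edgeR p under 0.05. The main fit gave 676, against 646 expected by chance. For the difference of responses they gave 185 and 246, and the main fit 77. In all 12 libraries the best correlate had the same number, a hint from the data and not the design.

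Of the lists, 8, 6, 8, 10 and 5 were called in the order LPS in Control, LPS in Runx1KO, genotypes with vehicle, genotypes with LPS and difference of responses. With an estimated correlation and with fry 0, 0, 1, 1 and 0 were called. Library size alone called 11 for LPS in Runx1KO. Without the libraries of 1 number 2 to 9 lists were called for LPS in Runx1KO, 5 to 10 for the genotypes with vehicle and 6 to 13 with LPS. In every comparison, such fits also called lists that were not called with all libraries.

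Camera's direction turned for 2 called lists, NF-kB for LPS in Runx1KO and immediate-early for the difference of responses, both without the libraries numbered 3. The median of 2 other called lists turned while camera's direction did not: oxidase and effectors for LPS in Runx1KO without the libraries numbered 3 (−0.033) and ribosomal proteins for the genotypes with vehicle without those numbered 2 (−0.020). For lists not called, values are given where camera's direction turned. List values are medians of log2 fold changes in the voom fit. Camera compares a list with all other genes, so its direction can turn while the median keeps its sign. With library size alone, LPS in Control gave −0.095 for ribosomal proteins, −0.14 for ribosome biogenesis, −0.15 for the unfolded protein response, −0.080 for mitochondrial transcripts and −0.42 for eosinophils. LPS in Runx1KO gave −0.18 for Tlr4, −0.38 for adhesion receptors, −0.35 for cell cycle, −0.38 for ribosome biogenesis and −0.56 for eosinophils. The genotypes gave 0.11 for oxidase and effectors and 0.26 for dendritic cells with vehicle, and 0.41 for T and NK cells with LPS. The difference of responses gave −0.17 for Runx1, −0.24 for cell cycle, −0.23 for ribosome biogenesis, −0.30 for eosinophils and −0.15 for T and NK cells. With the replicate block, LPS in Control gave −0.062 for interferon-stimulated genes and −0.067 for progenitors, and the genotypes gave −0.082 for dendritic cells with vehicle and 0.30 for T and NK cells with LPS. For the difference of responses the block gave −0.0044 for Runx1, 0.027 for ribosome biogenesis and 0.078 for eosinophils. Fry's direction differed from camera's for the tertiary granule (−0.13), oxidase and effector (0.031) and dendritic cell (0.15) lists for the genotypes with vehicle. It also differed for ribosome biogenesis (0.019) for the difference of responses. Fry uses the same fit, so these medians are those of the main voom fit and did not change. RLE scaling gave 0.18 for dendritic cells with vehicle. The Runx1 difference of responses was −0.0044 with RLE scaling, −0.0041 by DESeq2 and −0.024 without a low-count filter. That of Tnf was −0.37 by limma-voom and −0.51 with the replicate block within genotype.

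Further ranges of lists are over the fits that left out all libraries of 1 number. Those of single genes are over the fits that left out 1 library or all libraries of 1 number. In the LPS comparison in Control the ranges were −0.056 to −0.018 for interferon-stimulated genes, −0.050 to 0.051 for cell cycle, −0.069 to 0.070 for ribosomal proteins, −0.048 to 0.11 for ribosome biogenesis and −0.14 to 0.16 for mitochondrial transcripts. They were −0.0028 to 0.18 for monocytes, −0.50 to 0.12 for basophils and mast cells, 0.023 to 0.89 for platelets, −0.099 to 0.076 for progenitors and −0.82 to 0.13 for Tlr4. In the LPS comparison in Runx1KO the ranges were −0.50 to 2.41 for NF-kB, −0.040 to 0.28 for Toll-like receptors, −0.082 to 0.042 for cell cycle, −0.30 to 0.079 for ribosome biogenesis and −0.031 to 0.18 for the unfolded protein response. They were −0.12 to 0.51 for apoptosis regulators, −0.24 to 0.12 for glycolysis, −0.44 to 0.020 for RUNX genes, −0.61 to 0.53 for eosinophils and −0.67 to 0.35 for T and NK cells. They were −0.028 to 0.054 for platelets, −0.30 to 0.52 for dendritic cells and −0.15 to 0.36 for Tlr4. In the genotype comparison with vehicle the ranges were −0.18 to 0.91 for cytokines, −0.14 to 0.42 for interferon-stimulated genes, −0.48 to 0.063 for immediate-early genes, 0.028 to 0.34 for primary granule and −0.14 to 0.023 for tertiary granule. They were −0.089 to 0.061 for adhesion receptors, 0.015 to 0.098 for oxidase and effectors, −0.10 to 0.23 for ribosome biogenesis, −0.071 to 0.063 for RUNX genes and −2.21 to −0.060 for eosinophils. They were 0.13 to 0.57 for T and NK cells, −0.35 to 0.63 for dendritic cells, −0.074 to 1.52 for Tnf and −0.70 to 0.24 for Il1b. In the genotype comparison with LPS the ranges were −0.28 to 0.53 for NF-kB, −0.063 to 0.48 for oxidase and effectors, 0.054 to 0.23 for ribosome biogenesis, −0.14 to 0.17 for RUNX genes and −0.90 to 0.56 for eosinophils. They were −0.39 to 0.51 for T and NK cells, −0.48 to 0.36 for dendritic cells, −0.021 to 1.86 for Tnf and −0.25 to 0.82 for Il1b. In the difference of responses the ranges were −0.51 to 1.36 for cytokines, −0.92 to 0.29 for NF-kB, −0.15 to 0.11 for Toll-like receptors, −0.057 to 0.98 for immediate-early genes and −0.45 to 0.57 for oxidase and effectors. They were −0.083 to 0.10 for cell cycle, −0.096 to 0.046 for ribosome biogenesis, 0.025 to 0.080 for the unfolded protein response, −0.21 to 0.15 for apoptosis regulators and −0.062 to 0.16 for glycolysis. They were −0.13 to 0.11 for RUNX genes, −0.16 to 0.36 for eosinophils, −0.10 to 0.31 for B lineage, −0.56 to −0.085 for platelets and −0.21 to 0.33 for Runx1. They were −0.52 to 1.33 for Tnf and −0.55 to 1.38 for Cd14.

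Among 76 named gene results limma-voom ended 9 calls, a minimum fold of 1.5 ended 12, the fit of only 2 groups 19, library size alone 6 and RLE scaling 1. The filter at 5 CPM ended 4 calls and left 67 results unchanged. Named genes that this filter removed were not tested there and are in neither count. The block added 1, Tlr4 with LPS.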

Other observations

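The tests of DNA near Runx1 and of neighbouring genes were chosen only after the result was seen; those of platelets, scaling and the other splits were not. The genes named in this part were chosen after their values were seen.

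The transcripts of Acod1, Sod2, Cxcl10 and Csf3 had higher mean levels with LPS in both genotypes, with wide spread between libraries. Acod1, which makes itaconate, averaged 1376 and 3820 CPM in Control with vehicle and LPS and 1200 and 4860 CPM in Runx1KO. Sod2, the mitochondrial superoxide dismutase, averaged 364 and 1171 CPM in Control and 761 and 2805 CPM in Runx1KO. Cxcl10, a chemokine of the interferon response, averaged 25.1 and 155 CPM in Control and 61.9 and 766 CPM in Runx1KO. Csf3, the granulocyte growth factor, averaged 0.841 and 6.83 CPM in Control and 5.99 and 121 CPM in Runx1KO, where the LPS libraries numbered 1, 2 and 3 held 2.65, 32.2 and 329 CPM. None of these passed edgeR's test for LPS, and none for genotype (smallest adjusted p = 0.434, Csf3 with LPS).

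Haemoglobin transcripts had higher mean levels in Runx1KO beside the platelet transcripts, but not in each library. Hba-a1, which shares reads with a near-identical copy, held 307, 104 and 76.8 CPM in the Control vehicle libraries numbered 1, 2 and 3 and 491, 760 and 58.5 CPM in the Runx1KO vehicle libraries, and it did not pass (edgeR adjusted p = 0.910 with vehicle and 0.685 with LPS). Gata1, a transcription factor of red cells and megakaryocytes, averaged 0.386 and 1.91 CPM with vehicle (log2 fold change 2.29, edgeR adjusted p = 0.142). Among adhesion genes, the integrin subunit gene Itga4 averaged 14.3 and 39.1 CPM with vehicle and 19.1 and 60.9 CPM with LPS, and Itgax 13.5 and 5.13 CPM with vehicle; both passed edgeR's test only with the replicate block (adjusted p = 0.0230 and 0.0294 with vehicle). The chemokine gene Ccl2 averaged 0.450 CPM in Control and 62.1 CPM in Runx1KO with LPS (log2 fold change 7.10, adjusted p = 0.0628; 0.0310 with the block).

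Megakaryocyte and platelet transcripts were higher in Runx1KO libraries, with Pf4 at 11.03 CPM with vehicle and 12.5 CPM with LPS. The tables argue against scaling as the cause, since the median of the list was 2.55 or more in both treatments with library size alone. Platelets or megakaryocytes, of which the gate for CD11b and Ly6G would remove those not attached to a neutrophil, stay open as a candidate source: the median of 16 abundant platelet transcripts outside the list was 1.81 with vehicle and 1.72 with LPS, 32.5% and 40.1% of the median of the called markers, between the bounds set for and against; dividing by markers selected for being called lowers this share. Of these 16, 3 were called higher in both treatments (Cavin2, Alox12 and Gp5), and the 12 under 5 CPM in Control, looked at after the result was seen, had medians of 2.28 and 2.48 with 11 and 12 positive, while the most abundant transcripts with vehicle, Plek (1230 and 1490 CPM in Control and Runx1KO) and Cd9 (1180 and 749 CPM) outside the list and Itgb3 (28.4 and 17.6 CPM) in it, had a high Control level that would hide a small share of platelets. Expression by neutrophils without Runx1 was not tested and stays open too.

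The genotypes differed in 123 genes with vehicle and 119 with LPS. DNA carried along with the Runx1 allele may account for a few of them: on the GRCm38 assembly 6 of 119 called genes with LPS (5.04%) and 3 of 122 with vehicle (2.46%) lay among the 200 tested genes nearest Runx1, against 1.62% of all tested genes. Chromosome 16 as a whole held 3.13% of tested genes, so these 200 reach far from Runx1. The 8 called genes of this chromosome with LPS included Fam162a, Stfa2l1, Gm5483, Stfa2 and Stfa3. Each of these had another of them as a close neighbour, and the Stfa genes share reads, so they are not separate cases. Over all chromosomes, that of Runx1 included, 10 of 122 called genes with vehicle (8.2%) and 16 of 119 with LPS (13.4%) had another called gene among the 2 nearest on each side, where the upper end of the central 95% of 10000 random sets was 12 and 10. Such neighbours had the same direction in 10 of 10 and 14 of 16 cases, as with Pf4 and Ppbp, Dmpk and Dmwd, and Ldha and Ldhc, but several are near-identical genes that share reads, such as Stfa2 and Stfa3, and the treatments part, so the test does not decide. An effect of Runx1 loss on these genes stays open as the difference the design names.

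Each comparison of 3 against 3 libraries allows 10 splits, the real one included, too few for a share under 0.05. The real split gave 123 genes for the genotypes with vehicle and 119 with LPS, where the highest other split gave 0 in each. For LPS in Control the real split and the highest other gave 0, and the same held for the difference of responses. In the 3 comparisons whose numbers pair, the 3 other splits that part all 3 pairs gave 0. For LPS in Runx1KO the real split gave 0 and the highest other 581, a split that set vehicle 1, vehicle 3 and LPS 1 against vehicle 2, LPS 2 and LPS 3 and points to a structure of the samples that differs from the treatment labels. The same split orders these libraries by the mean level of the NF-kB list, −2.39, −1.30 and 0.14 against 0.75, 1.37 and 2.16 log2, so a response to stimulation is not excluded as that structure. The count of splits as large as the real one, itself included, was 1 for each genotype comparison.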
